A study of Rattus norvegicus with 8 samples.

How the data were processed

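Expression was measured in motoneurons of the lumbar spinal cord of Wistar albino rats. Per the labels' protocols, cryostat sections of 12 µm were stained with cresyl violet, a dye by which the large motoneurons are recognised, and 1500 to 2000 of these cells were collected by laser capture for each array. Total RNA was purified, about 50 ng came from each pool of 4 rats, and it was amplified in 2 rounds of reverse transcription and in vitro transcription primed at the poly(A) tail before biotin labelling, per the labels' protocols. Amplification of this kind favours the 3′ ends of transcripts, so probe sets far from a 3′ end can read low. The design text states that animals of 4 litters were divided between the 2 ages, which gave 4 replicates at postnatal day 1 (P1) and 4 at postnatal day 21 (P21), 1 Affymetrix RAE230 2.0 array each.

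The table the authors deposited holds a linear intensity for each of 31042 probe sets on each of the 8 arrays, with 0 missing values. How the authors summarised the probes, corrected the background and normalized the arrays is not given in the sources used here. The array medians lay between 323 and 416 and the arrays did not share 1 distribution, so the deposited intensities were not fully quantile normalized. Between 66 and 250 values per array were below 0. The table contained 0 control probe sets, so signs of RNA quality from 5′ and 3′ control probes, which were to be reported, are not analysed here. For arrays, depth is not defined, and the number of arrays limits the precision.

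Probe sets were named through the platform's annotation table, with symbols updated by gene identifier from a table of the current rat assembly, GRCr8. Of the probe sets, 20826 had 1 symbol, 436 had several and 9780 had none. The gene identifier of 20758 of the probe sets with 1 symbol was found in the current table, the other 68 kept the symbol of the platform annotation, and 0 symbols changed. Probe sets with several symbols or none entered the probe-set counts and named no gene. No genomic coordinates are printed, since the probe annotation names no assembly.

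Intensities below 0 were set to 0, and log2(intensity + 16) was tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), comparing P21 with P1 over all 8 arrays with no covariate. Fold changes are on this scale, which understates the change of dim genes. A probe set was kept if its intensity exceeded the 40th percentile of its array on at least 4 of the 8 arrays, which left 19155. P-values were adjusted by the Benjamini-Hochberg method over the kept probe sets, and an adjusted p under 0.05 counted as a call. Every adjusted p of a gene comes from this limma test. Where all 4 intensities at 1 age lay below that percentile of their arrays, the change is given as at least N-fold, the mean at the brighter age against the mean level of the percentile on the arrays of the dimmer age, both on the log2 scale.

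Each gene was represented by its kept probe set of highest mean among those with exactly 1 symbol, which gave 10961 genes. Lists of genes were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, and by camera with an estimated correlation. A list needed at least 5 measured genes. Adjustment was over the 34 lists, of which 25 were functional and 9 were markers of other cell types. The rotation test fry, which asks whether a list's own genes moved 1 way on balance without comparing them with other genes, was run beside them. Each list's median change was also set among 10000 random lists matched on mean level, a comparison added after the data were seen.

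The tests, lists, thresholds, alternatives and the rule for the genes to name were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among called genes whose 4 intensities at 1 age all lay on 1 side of the 4 at the other. From each list it took the 2 called members with the largest change in the prevailing direction and the 1 with the largest change the other way. It also took fixed markers of motoneurons (Chat, Slc18a3, Slc5a7, Isl1, Gap43, Nefl, Nefm, Nefh), glia (Mbp, Gfap, Aif1), vessels (Cldn5) and interneurons (Gad1). A further fixed marker is not reported here. Further members of a list are named where they help to describe it, and these were chosen after their values were seen.

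The replicate numbers in the sample titles are shared by the ages. The deviations of same-numbered arrays from the mean of their age correlated across probe sets at 0.514, 0.321, 0.558 and 0.15 for numbers 1 to 4, so the numbers were taken to pair the arrays. The pairing is not clean, since the differently numbered P1 replicate 4 and P21 replicate 3 correlated at 0.366 and P1 replicate 1 and P21 replicate 2 at 0.262, both above the value for number 4. The pairing comes from these correlations and from the litters divided between the ages in the design text, which does not say that a number stands for a litter. The signs of the correlations also follow a grouping of numbers 1 and 2 against 3 and 4. Correlations were 0.068 to 0.514 among arrays numbered 1 and 2 and 0.068 to 0.558 among those numbered 3 and 4. Across these groups they were -0.458 to -0.235, except 0.038 for P1 replicate 2 with P21 replicate 4. Values below 16 numbered 173 to 223 on arrays numbered 1 and 2 and 348 to 680 on the others. These values do not tell litters from such a grouping. The fit without pairs is the one reported, and the fit with the replicate number as a block is an alternative.

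Alternatives were quantile normalization, centring each array on its median, no filter or a filter at the 60th percentile, pseudocounts of 1 and 64, the replicate block, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, and leaving out each array in turn, with the filter applied anew to the other 7. Leaving out each array on the same probe sets as with 8, using only arrays numbered 1 and 2 or only those numbered 3 and 4, and the level of Y-linked Eif2s3y as a covariate were added after the data were seen. The test was run on simulated data with 19155 probe sets of the measured means and spreads, 200 of them changed between P21 and P1. It recovered 27 of 67 changed by 0.5 on the log2 scale, 54 of 67 changed by 1 and 63 of 66 changed by 2, with 8 false calls. The data gave 7329 calls, so the Benjamini-Hochberg cutoff was stricter in the simulation, whose arrays were also drawn independently. These rates therefore do not carry over directly to the real comparison. In 30 simulated lists of 25 probe sets the list test recovered 5 of 5 raised lists with 0 false calls. These simulated lists had no correlation between genes. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.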

Results

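Spinal motoneurons, the cholinergic cells whose axons leave the cord to drive muscle, were compared between P1, while their axons are being myelinated, and P21, once myelination is over. Each age had 4 biological replicates, each a laser-captured pool of motoneurons on 1 array. The median intensity was between 323 and 408 on the P1 arrays and between 399.6 and 416 on the P21 arrays. Across the kept probe sets, arrays correlated at 0.958 to 0.986 within an age and at 0.821 to 0.868 between ages. Below, a change is log2 of P21 over P1, written ± its standard error, an intensity is written ± SD, and n = 4 arrays per age throughout.

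The comparison asked which transcripts differ between the captured motoneuron pools of the 2 ages. RNA of other cells captured with the motoneurons cannot be told apart from theirs, so a change need not lie in the motoneurons. By fitted change the rises were headed by Mobp, a protein of compact central myelin, which went from an intensity of 9.05 ± 13 at P1 to 4598 ± 443 at P21 (change 7.58 ± 0.29, at least 17.2-fold, adjusted p = 2.23e-07). Opalin, another oligodendrocyte protein, rose by 5.20 ± 0.16 (at least 4.94-fold). The falls were headed by Ntf3, the neurotrophin NT-3, from 1282 ± 299 to -1.18 ± 13.3 (change -5.99 ± 0.24, at least 4.37-fold lower, adjusted p = 3.11e-07). Stx1a, a SNARE protein of vesicle fusion, fell from 2482 ± 201 to 76.2 ± 101, at least 8.58-fold. All 4 of these genes were separated completely between the ages.

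Genes with all 4 intensities of 1 age under the filter level are ranked against a floor, so the order among them was not measured and their folds are bounds. The other leading rises were at least 1.91-fold for Lims2, 4.73-fold for S100a9, 1.56-fold for Lcp2, 3.03-fold for Krt13, 6.05-fold for Tmod1, 6.87-fold for Bace2 and 7.86-fold for Irag1, and Plxdc1 went from 183 ± 56.5 to 3705 ± 150, with 3 of its 4 P1 intensities under the filter level. Bace2 is a protease related to the secretase that cleaves the amyloid precursor, and rose from 76.9 ± 35.4 to 1834 ± 253. S100a9, a calcium-binding protein abundant in myeloid cells, had the widest spread of these at P21, 1798 ± 1918, where P21 replicate 4 read 4640, and its fitted change went from 4.93 to 4.31 without that array. The other leading falls were at least 2.86-fold for the neuropeptide gene Nmu, 4.50-fold for Nrsn2, 2.57-fold for Bend5, 2.06-fold for the chemokine receptor gene Ccr6, 6.18-fold for Tmem91, 4.21-fold for Cpxm1, 3.91-fold for Arhgap25 and 2.03-fold for Gnmt.

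Of 10961 genes tested, 4317 passed limma's test, 2411 higher and 1906 lower at P21, and 1132 of them changed at least 2-fold (651 higher, 481 lower). Among the 19155 probe sets, 7329 passed (3990 higher, 3339 lower) and 1918 changed at least 2-fold. In 4399 genes (40.1%) the 4 intensities at 1 age all lay on 1 side of the 4 at the other, against 2.86% given by chance. The share of called probe sets that were higher at P21 was 54.4%, but 38.6% when each array was centred on its median, a change that moved the median of all probe sets from 0.07 to -0.07. The sign of changes smaller than that depends on the scaling, and the list test, which sets a list against all other genes, is relative to that shift. The test called 3385 probe sets with only the arrays numbered 1 and 2 and 5834 with only those numbered 3 and 4, comparisons chosen after the data were seen.

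**Figure D1:**
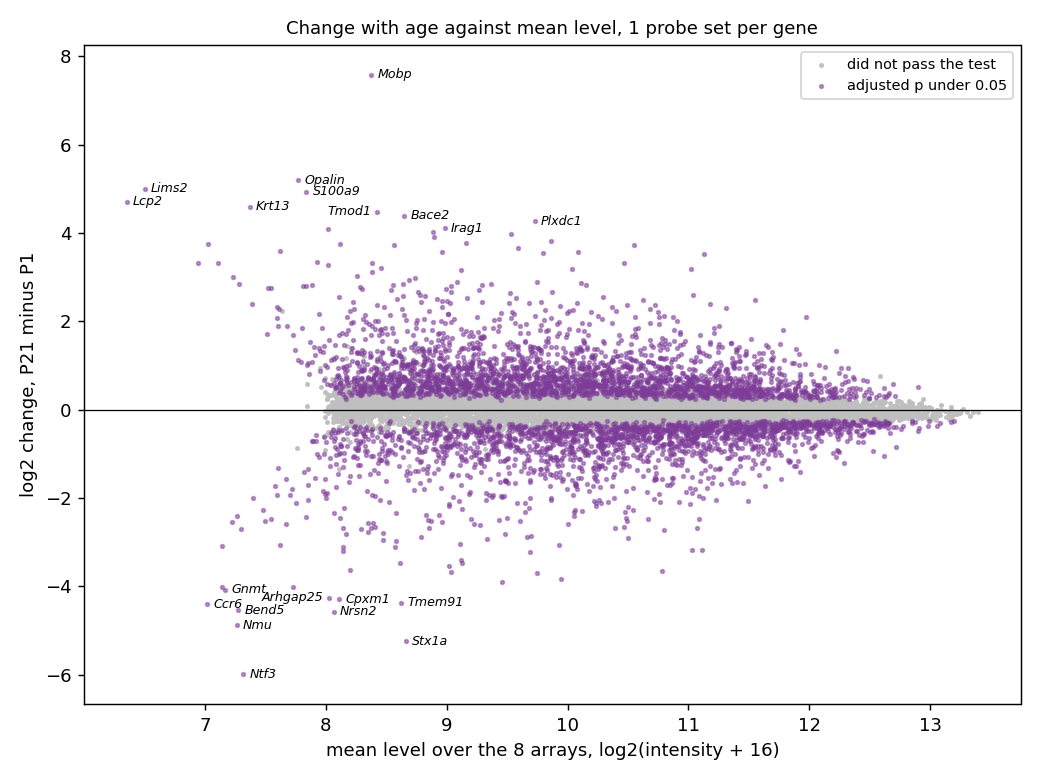
Change with age (P21 minus P1, log2 of intensity + 16, vertical axis) against the mean level over the 8 arrays (horizontal axis, same log2 scale), with 1 point per gene for 10961 genes. Coloured points are the 4317 genes with an adjusted p under 0.05, and the names mark the 10 highest fitted changes, with Mobp at 7.58, and the 10 lowest, with Ntf3 at -5.99.

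Of the 34 lists, 12 passed camera with the preset correlation, 4 higher and 8 lower at P21. With an estimated correlation 0 of the 34 passed, so that p is given with each. Other splits of the same 8 arrays passed up to 14 lists, although each called 0 probe sets with limma's test (up to 3196 at an unadjusted p under 0.05). For that reason the members that passed on their own are given first. These counts rest on 1 probe set per gene, and another probe set of some counted members was called the other way. Dlg4 counted as a fall (-0.75) with another probe set at 0.54, and Sema5a as a fall (-0.48) with another at 0.88. Over all genes, 66 of 614 with at least 2 called probe sets had such opposed calls. Counts adjusted over the list alone were those given for each list except where stated.

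Of 25 genes of oligodendrocytes and myelin measured, 20 rose, 1 fell and 4 did not pass, with a median change of 1.61 (camera adjusted p = 4.98e-11, adjusted p = 0.0699 with an estimated correlation). Mbp, the basic protein of myelin, rose from 2002 ± 606 to 8290 ± 705 (4.27-fold), while its other kept probe sets had changes of 1.65, called, and 0.15, not called. Mog rose at least 10.9-fold, and Mag and Cnp rose by 1.61 and 1.25. Qdpr, an enzyme that recycles tetrahydrobiopterin, was the member that fell (-0.37 ± 0.11, adjusted p = 0.0289), and its adjusted p lay between 0.0553 and 0.0824 without P1 replicate 1, 3 or 4 or P21 replicate 1 or 4, and was 0.0605 without the filter. In the list of oligodendrocyte precursors, 7 measured, 3 rose and 2 fell, the median (-0.07) and the mean (0.27) differed in sign, and the camera direction was up with an adjusted p of 0.749. Bcas1 (1.74) and Sox10 (0.98) rose and Ptprz1 fell (-0.88, with its other kept probe set at -0.31 and not called).

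Markers of other cells also moved. Of 13 microglial and macrophage genes, 9 rose and 1 fell, with a median of 1.05 (camera adjusted p = 0.00893, adjusted p = 0.468 with an estimated correlation). Without the filter that median was 0.474 (camera adjusted p = 0.0649). Lyz2, lysozyme, rose from 124 ± 92.9 to 2003 ± 872 and Cd74, the invariant chain, at least 1.78-fold, while Cd53 fell (-0.59 ± 0.15, at least 1.34-fold) and Aif1 did not differ by the test (851 ± 246 and 869 ± 154). Of 22 endothelial and pericyte genes, 9 rose and 0 fell, with a median of 0.63 (camera adjusted p = 0.0202, adjusted p = 0.646 with an estimated correlation). That call was lost without P21 replicate 2 (adjusted p = 0.0506, or 0.0564 on the same probe sets), with quantile normalization (0.0529) and with the filter at the 60th percentile (0.0773). Col1a2 (1.76 ± 0.41) and Col1a1 (1.35 ± 0.35) led that list. Both read highest on P21 replicate 4 (8464 and 8626, against means of 2774 and 3544 on the other P21 arrays), as did Lyz2 (3278 against 1578), and without it Col1a2 rose by 1.35 (adjusted p = 0.00703) and Col1a1 by 1.02 (adjusted p = 0.0145). Cldn5 of endothelial tight junctions did not pass (1735 ± 495 and 2163 ± 715). Of 7 erythrocyte genes, 4 rose and 0 fell, with a median of 0.76 (camera adjusted p = 0.0214, adjusted p = 0.416 with an estimated correlation), led by Ahsp (2.66) and Alas2 (1.93). The erythrocyte median was 0.435 without the filter (camera adjusted p = 0.0831).

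Among astrocyte genes, 12 of 23 rose and 2 fell, with a median of 0.37 (camera adjusted p = 0.117). The connexin gene Gjb6 rose from 116 ± 103 to 1367 ± 201, Ntsr2 rose by 1.78 ± 0.13 and Gfap by 1.53 ± 0.17, whereas the glutamate transporter gene Slc1a3 (-1.35 ± 0.18) and Fabp7 (-1.21) fell. Of 9 Schwann cell genes, 6 rose and 2 fell (median 0.52, camera adjusted p = 0.311), with Pmp2 (2.00) and Prx (1.33) up and Ngfr and Pou3f1, which are also on lists of neuronal genes, down. Of 14 genes of spinal interneurons, 7 fell, 3 rose and 4 did not pass (median -0.53, camera adjusted p = 0.0722). The peptide genes Tac1 (at least 3.39-fold) and Sst (-2.65 ± 0.34) fell and Cck rose (1.12 ± 0.10). Gad1, which makes GABA, fell by 0.56 ± 0.19 (adjusted p = 0.0444), but the adjusted p was 0.0709 with the replicate block, 0.0811 without the filter and 0.914 with the mean of its 2 probe sets, and it lay between 0.0540 and 0.103 without P1 replicate 1, 2, 3 or 4 or P21 replicate 1, 2 or 4. Of 23 genes of dividing cells, 6 fell and 1 rose (median -0.11, camera adjusted p = 0.0737), led by Mcm6 (at least 1.16-fold) and Cdk1 (-1.19), and Mcm4 rose (0.35 ± 0.09), a call lost when arrays were centred on their medians (adjusted p = 0.256).

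The list of motoneuron and cholinergic identity was divided, with 5 of 20 genes rising, 9 falling and 6 not passing (median -0.21, camera adjusted p = 0.225). Chat, which makes acetylcholine, rose from 1377 ± 244 to 3451 ± 450 (change 1.32 ± 0.14, adjusted p = 8.66e-05). Its neighbours in cholinergic transmission did not differ by the test. The vesicular transporter gene Slc18a3 read 4103 ± 644 and 3770 ± 1033 (change -0.15, adjusted p = 0.585), and the choline transporter gene Slc5a7 read 4698 ± 379 and 5003 ± 336. Tns1 rose (1.42 ± 0.11). The transcription factor genes Isl1 (-1.67 ± 0.24), Pou3f1 (-1.28) and Foxp1 (-1.22) fell, and Aldh1a2, which makes retinoic acid and marks limb motor columns, fell from 6243 ± 619 to 528 ± 218 (12.6-fold lower, adjusted p = 2.88e-05).

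Most cytoskeletal genes of mature axons did not pass the test. Of 19 measured, 3 rose, 2 fell and 14 did not pass, or 2 and 2 adjusted over the list alone, with a median of -0.03 that was 0.02 with quantile normalization (camera adjusted p = 0.501). The neurofilament genes did not differ by the test, with changes of 0.07 ± 0.08 for Nefl, -0.06 ± 0.08 for Nefm and 0.00 ± 0.08 for Nefh. Their intensities lay near the highest on the arrays (10572 to 11540), a range in which probes can saturate, so these values do not exclude a change. Kif5b, a kinesin heavy chain, rose (0.62 ± 0.10, with its other kept probe set at 0.26 and not called), Mapt, the tau gene, fell from 8098 ± 286 to 4285 ± 549, and Dst rose by 0.31 ± 0.08, a call lost on centring (adjusted p = 0.260) and with the mean of its 2 probe sets (0.188).

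Of 24 genes of axon growth and the immature cytoskeleton measured, 14 fell, 1 rose and 9 did not pass, with a median of -0.33 (camera adjusted p = 2.96e-04, adjusted p = 0.592 with an estimated correlation). Dcx, doublecortin, fell from 3106 ± 496 to 223 ± 19.8, at least 10.6-fold, and the collapsin response mediators Dpysl5 (-1.27 ± 0.15), Dpysl4 (-1.19) and Crmp1 (-1.06) fell, while Dpysl2 (-0.10) and Dpysl3 (0.08) of that family did not pass. Gap43, the growth cone protein, fell by 0.37 ± 0.09 (adjusted p = 0.00770), from 9154 ± 249 to 7108 ± 461. The P1 level is close to that of the neurofilament genes, where saturation can understate a fall. Cd24 was the member that rose (0.46 ± 0.11, adjusted p = 0.00747, 0.109 on centring).

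Of 33 axon guidance genes, 17 fell, 4 rose and 12 did not pass, or 20 fell and 6 rose adjusted over the list alone (median -0.37, camera adjusted p = 0.00160, adjusted p = 0.468 with an estimated correlation). The ephrin gene Efnb3 fell by 2.55 ± 0.20, and the receptor gene Epha4, which steers motor axons in the limb, fell from 5510 ± 691 to 2433 ± 178, while the semaphorin gene Sema4d rose at least 3.51-fold. Of 26 developmental neuronal transcription factors, 14 fell and 4 rose (median -0.47, camera adjusted p = 0.00411, adjusted p = 0.416 with an estimated correlation). Onecut1 (at least 3.20-fold), Bcl11a (at least 2.88-fold), Meis2 (-2.46) and Meis1 (-1.91) fell, and Zfhx4 rose (1.57 ± 0.19). That list's call was lost with only the arrays numbered 1 and 2 (adjusted p = 0.0816). The spinal interneuron list, with 7 of 14 genes falling, had a median of -0.53 over all 8 arrays.

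Hox genes, which set position along the cord, went both ways, with 5 of 19 rising and 4 falling, or 7 and 5 adjusted over the list alone. Hoxc9 (at least 1.38-fold) and Hoxd8 (1.16 ± 0.13) rose, and Hoxa11 fell from 1893 ± 282 to 459 ± 152. The median was 0.01, or -0.12 when arrays were centred, and the camera direction was down with an adjusted p of 0.921. Among RNA-binding proteins and splicing factors, 14 of 36 fell and 2 rose, or 17 and 2 adjusted over the list alone (median -0.22, camera adjusted p = 0.00160, adjusted p = 0.468 with an estimated correlation). Igf2bp3, a messenger RNA-binding protein of developing tissue, fell at least 4.47-fold and Khdrbs2 from 719.7 ± 210.1 to 222 ± 32.2, at least 2.46-fold. Tardbp, the gene of TDP-43, rose by 0.68 ± 0.14 on the probe set used, while its other kept probe set fell (-0.42), and the mean of the 2 did not pass (adjusted p = 0.403).

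**Figure D2:**
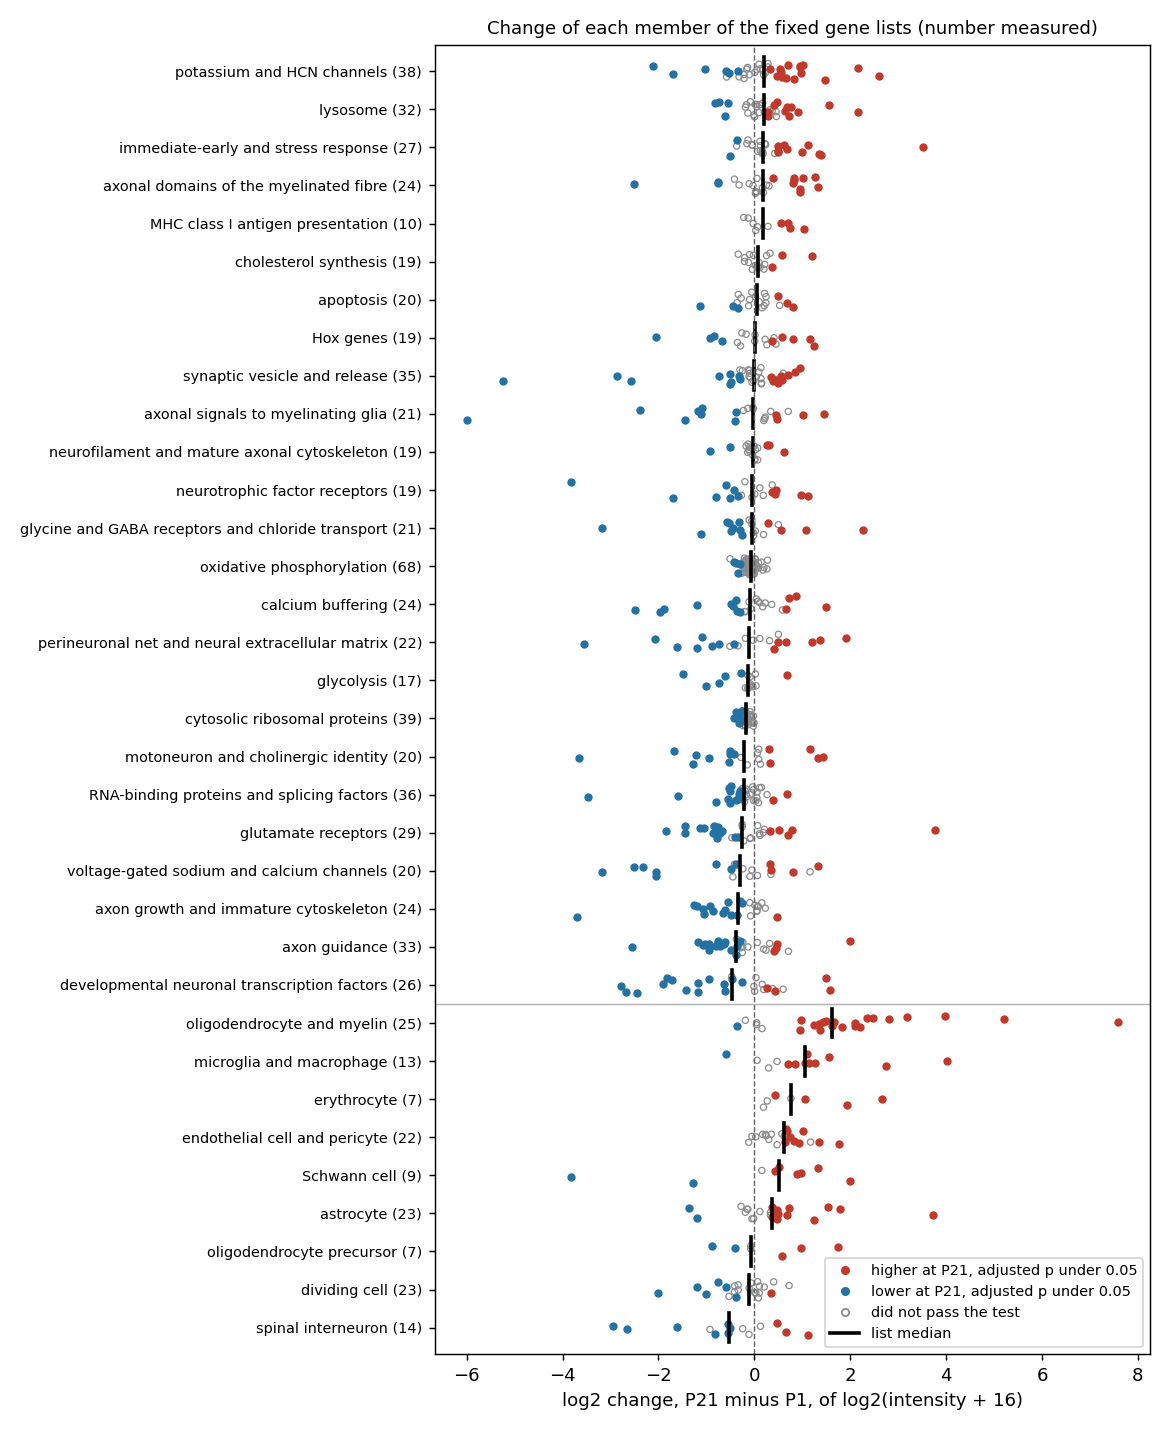
Change with age (P21 minus P1, log2 of intensity + 16, horizontal axis) of each measured member of the 34 gene lists, 1 row per list with its number of measured genes. Filled points passed the test, open points did not, and black bars are list medians, from 1.61 for oligodendrocyte and myelin genes to -0.53 for spinal interneuron genes.

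Sodium channel genes moved in both directions. Scn2a fell from 3426 ± 228 to 608 ± 182, the auxiliary gene Scn3b fell by 3.19 ± 0.22 and Scn3a by 2.04, while Scn4b rose from 2983 ± 116 to 7558 ± 328 (change 1.34 ± 0.08) and Scn1a by 0.81. Of 20 sodium and calcium channel genes, 4 rose and 8 fell, or 6 and 8 adjusted over the list alone (median -0.31, camera adjusted p = 0.0722). Of 38 potassium and HCN channel genes, 16 rose and 6 fell (median 0.21, camera adjusted p = 0.158). The inward rectifier genes Kcnj14, from 841 ± 61.4 to 5160 ± 247, and Kcnj12, by 2.17 ± 0.16, led the rise, and Kcna6 fell (-2.12 ± 0.19), while its other kept probe set had a change of 0.17 that did not pass.

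Among proteins of the axonal domains of myelinated fibres, 9 of 24 rose and 3 fell (median 0.18, camera adjusted p = 0.117). Besides Scn4b, the spectrin gene Sptbn4 of nodes and initial segments rose by 1.26 ± 0.13, and the juxtaparanodal channel genes Kcna1 (0.94) and Kcna2 (0.82) rose, with their auxiliary genes Kcnab1 (0.95) and Kcnab2 (1.02). The myelin list had a median of 1.61 on the same arrays.

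Glycine receptor subunit genes moved apart. Glra2, the subunit of immature neurons, fell from 6260 ± 170 to 777 ± 417, and Glra1, that of adult cord, rose from 191 ± 138 to 1027 ± 785 (change 2.27 ± 0.51, adjusted p = 0.00628). Glra1 read 446 to 2186 on the P21 arrays and 395 on P1 replicate 1, while the other P1 arrays lay under the filter level. In that list of glycine, GABA and chloride genes, 4 of 21 rose and 9 fell, Gabrb1 among them (-1.10 ± 0.20), with a median of -0.05 and a camera adjusted p of 0.257. Glutamate receptor and scaffold genes fell in 13 of 29 cases and rose in 5, or fell in 14 and rose in 5 adjusted over the list alone (median -0.25, camera adjusted p = 0.0214, adjusted p = 0.646 with an estimated correlation). The scaffold genes Grip1 (at least 1.64-fold) and Shank2 (-1.45 ± 0.15) and the AMPA receptor gene Gria1 (at least 1.45-fold) fell, whereas the NMDA receptor gene Grin3b rose from 139 ± 13.4 to 2105 ± 209, at least 7.90-fold. The list's adjusted p was 0.0628, 0.135, 0.0882 and 0.0591 without P1 replicate 1, 2, 3 and 4, where filtering anew also removes members bright at P1 alone, such as Grip1. On the same probe sets the call was lost without P1 replicate 3 (adjusted p = 0.0541) and with no other array left out. The adjusted p was 0.0773 with the filter at the 60th percentile.

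**Figure D3:**
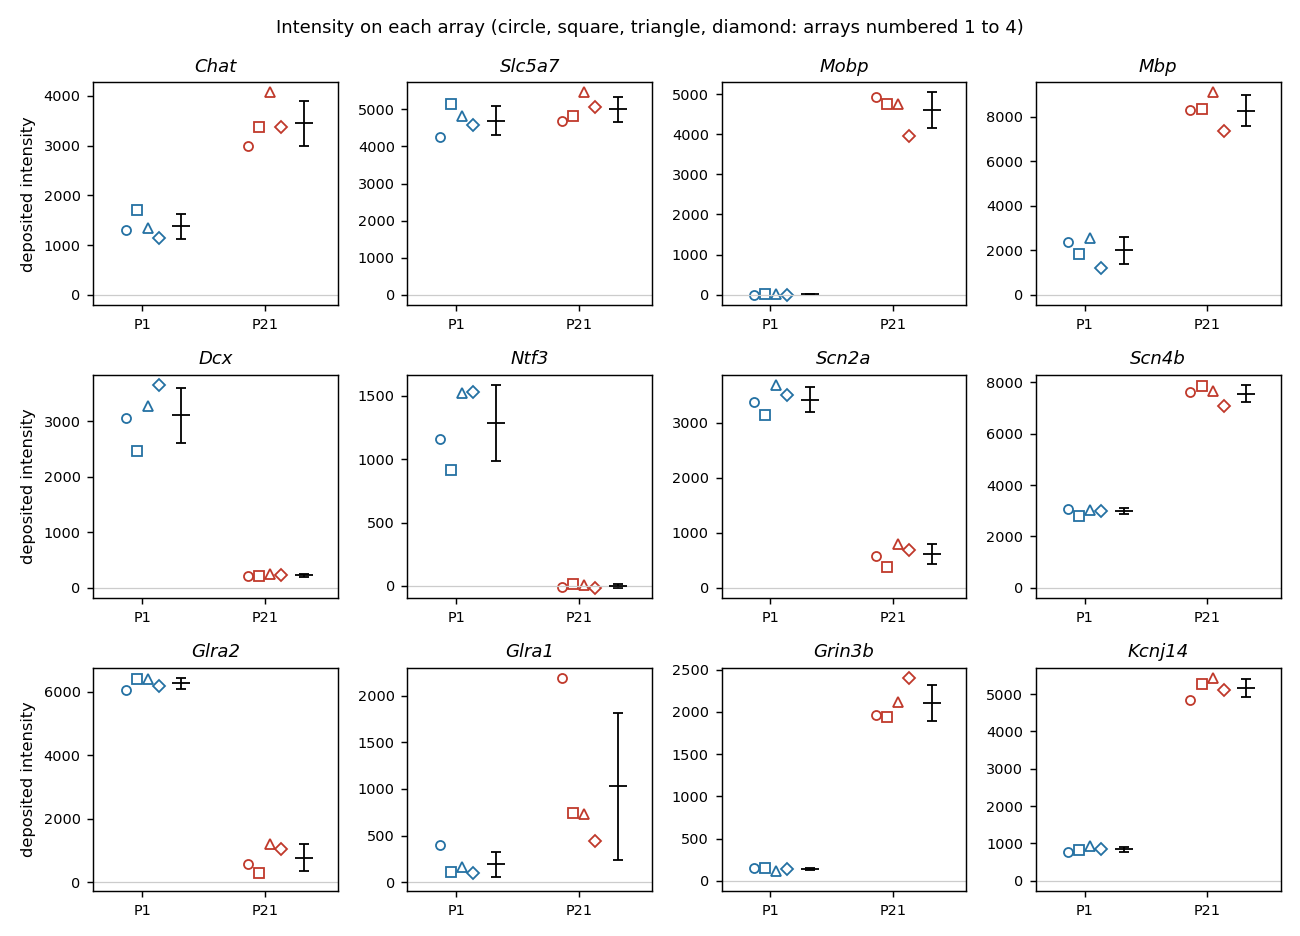
Deposited intensity (vertical axis, linear) of 12 genes on each array at P1 and P21, with symbols for the arrays numbered 1 to 4 and black marks for the mean and SD of 4 arrays. Scn2a falls from 3426 to 608 and Glra2 from 6260 to 777, whereas Scn4b rises from 2983 to 7558 and Chat from 1377 to 3451.

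Synaptic vesicle genes were divided, with 9 of 35 rising and 9 falling (median -0.01, or 0.01 with quantile normalization, camera adjusted p = 0.546). Besides Stx1a, Cplx2 (-2.86) and Syt5 (at least 2.73-fold) fell, while Rab3b rose from 2162 ± 133 to 4228 ± 349. Syn2 rose by 0.84 ± 0.13 on the probe set used, another of its probe sets fell (-0.58), and the mean of the 3 did not pass (adjusted p = 0.326).

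Of 21 genes for axonal signals to glia, 8 fell and 4 rose, or 8 and 6 adjusted over the list alone (median -0.03, mean -0.44, camera adjusted p = 0.265). Besides Ntf3, the neurotrophin gene Bdnf fell from 1032 ± 144 to 187 ± 44.3, at least 3.58-fold, and Fgf1 rose from 1928 ± 219 to 5298 ± 373. Nrg1, an axonal signal for myelin thickness, did not pass (-0.14). Neurotrophic factor receptors fell in 7 of 19 cases and rose in 5 (median -0.05, camera adjusted p = 0.360). The neurotrophin receptor gene Ngfr fell from 3731 ± 467 to 262 ± 113, with 3 of 4 P21 intensities under the filter level, and Gfra2 fell by 1.70 ± 0.11, with its other kept probe set higher at P21 (0.59). Fgfr2 rose by 1.11 ± 0.08, and its other kept probe set had a change of 0.20 that was not called.

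In the list of perineuronal net and matrix genes 6 of 22 rose and 8 fell, or 8 and 8 adjusted over the list alone (median -0.10, camera adjusted p = 0.546). The link protein gene Hapln4 rose from 1312 ± 483 to 4722 ± 198, while its other kept probe set had a change of 0.33 that was not called. Tnr rose by 1.36, whereas the glypican gene Gpc2 fell at least 6.10-fold and Tnc, tenascin C, fell by 2.08 ± 0.47. Calcium buffering genes fell in 9 of 24 cases and rose in 4, or 5 adjusted over the list alone (median -0.09, camera adjusted p = 0.239). Calb1, calbindin, fell from 1642 ± 327 to 290.1 ± 114 and Necab2 by 1.98 ± 0.13, and Itpr1, a calcium release channel gene, rose from 417 ± 29.0 to 1194 ± 32.5.

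Of 39 ribosomal protein genes, 9 fell and 0 rose, or 4 and 0 adjusted over the list alone (median -0.18, camera adjusted p = 5.92e-04, adjusted p = 0.662 with an estimated correlation). Rpl4 fell by 0.42 ± 0.09 and Rpl7 by 0.38 ± 0.09. Of 68 genes of oxidative phosphorylation 4 fell and 0 rose, and 0 passed limma's test adjusted over the list alone, with 9 at an unadjusted p under 0.05 (median -0.08, camera adjusted p = 0.0284, adjusted p = 0.780 with an estimated correlation). Atp5f1a fell by 0.42 ± 0.09, and Uqcrfs1 by 0.38 ± 0.11 (adjusted p = 0.0245), which had an adjusted p between 0.0541 and 0.0682 without P1 replicate 3 or 4 or P21 replicate 1 or 4 and 0.0525 without the filter. The list's adjusted p was 0.55 with quantile normalization, 0.0773 with the filter at the 60th percentile, and 0.0688, 0.152 and 0.0547 without P1 replicate 3, P21 replicate 1 and P21 replicate 2. On the same probe sets it was 0.0828, 0.0576 and 0.121 without P1 replicate 3, P1 replicate 4 and P21 replicate 1.

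Of 17 glycolysis genes, 5 fell and 1 rose (median -0.13, camera adjusted p = 0.0356, adjusted p = 0.662 with an estimated correlation). Ldha, lactate dehydrogenase A, fell from 5117 ± 407 to 1858 ± 439, the neuronal glucose transporter gene Slc2a3 fell by 1.00 ± 0.15, and Slc2a1, the transporter of vessels and glia, rose by 0.68 ± 0.11. The list's adjusted p was 0.225 with quantile normalization, 0.0511 on centring, 0.0773 with the filter at the 60th percentile, and 0.0627, 0.0657 and 0.0910 without P1 replicate 3, P21 replicate 1 and P21 replicate 4, or 0.0669, 0.0549 and 0.0812 on the same probe sets.

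Of 19 genes of cholesterol synthesis, 3 rose and 0 fell (median 0.08, or -0.06 on centring, camera adjusted p = 0.501), led by Ebp (1.21 ± 0.15) and Sc5d (0.57 ± 0.08). Lysosomal genes rose in 11 of 32 cases and fell in 4 (median 0.19, camera adjusted p = 0.195). Ctsz rose at least 1.94-fold and read highest on P21 replicate 4, Ctss, which the microglial list also holds, rose by 1.56 ± 0.17, and Glb1 fell by 0.82 ± 0.18. The microglial list had a median of 1.05 on the same arrays. Of 10 genes of MHC class I presentation, 4 rose and 0 fell (median 0.18, camera adjusted p = 0.311). B2m rose from 2085 ± 296 to 4278 ± 741 and RT1-S3 by 0.75 ± 0.18, a call lost with quantile normalization (adjusted p = 0.0552).

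Apoptosis genes were split evenly, with 3 of 20 rising and 3 falling (median 0.06, or -0.07 on centring, with the camera direction down and an adjusted p of 0.921). The protective genes Bcl2l2 (0.80 ± 0.12) and Xiap (0.67 ± 0.13) rose and the death-promoting gene Bbc3 fell (-1.14 ± 0.12), whereas the protective gene Mcl1 fell (-0.46) and the death-promoting gene Bnip3l rose (0.50). Immediate-early and stress genes rose in 10 of 27 cases and fell in 2 (median 0.19, camera adjusted p = 0.0722). The small heat shock protein gene Hspb1 rose from 675 ± 213 to 7595 ± 712 (11.5-fold, adjusted p = 4.88e-06), Gadd45b by 1.39 ± 0.15 and Hmox1 by 1.11. The activity-regulated genes Fos (0.12) and Arc (0.12) did not pass. Dusp6 fell by 0.50 ± 0.16 (adjusted p = 0.0306), and its adjusted p lay between 0.0503 and 0.0821 without P1 replicate 1, 3 or 4 or P21 replicate 2, 3 or 4, and was 0.0602 without the filter.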

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

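The splits of the arrays for the counts of probe sets, the difference between the myelin and astrocyte lists, the count of dim myelin genes without the filter and the random matched lists (after the lists' changes but before their percentiles) were tests chosen only after the results were seen. A sample was singled out where its gap to the nearest of the 4 arrays of its age, divided by their range, exceeded the 95% critical value of Dixon's test. Of 242 groups of 4 examined, 13 did so, where chance alone gives 1 in 20, or 12.1. Among the leading genes, Bace2 was high on P21 replicate 4 (gap 0.893, intensity 2212 against at most 1726), Bend5 low on P1 replicate 1 (0.968, 568 against at least 789) and Ccr6 high on P21 replicate 3 (1.00, 137 against at most -30.9). The gaps are of log2 values. On the deposited intensities 6 of the 13 were under the critical value: Ccr6 (0.558), whose gap arises because values below 0 were set to 0, Cd24 (0.821), Kcnj12 (0.818), Igf2bp3 (0.779), Hspb1 (0.776) and Ptprz1 (0.815). Aldh1a2 was low on P21 replicate 4 (0.980, 202 against at least 628), the same array on which Kcnj12 was low (0.838) and Tnc high (0.893, 2041 against at most 441). Isl1 was high on P21 replicate 3 (0.844, 366 against at most 210.1). On P1 replicate 1, Hspb1 was low (0.837, 361 against at least 729.5) and Xiap high (0.868). Cd24 was low on P21 replicate 1 (0.833), Epha4 low on P1 replicate 2 (0.935), and Igf2bp3 (0.847) and Ptprz1 (0.837) low on P21 replicate 2.

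Of the 35 ways to split the 8 arrays 4 against 4, 1, the real one, gave as many called probe sets, with 7329 against at most 0 in the others, and likewise 1 gave as many changed at least 2-fold, with 1918 against at most 0 (at an unadjusted p under 0.05, limma called up to 3196 in the others). Taken as equally likely, which disregards the pairs, the 35 splits argue against chance for both counts, at 1 in 35, the smallest share they can give. With same-numbered arrays taken as pairs, only the 8 splits that part every pair compare, too few for a share under 5%. With pairs, therefore, the splits cannot decide on chance for these counts. Every other split mixes the ages, so its 0 calls do not show how many would arise with no age difference. Chance cannot be excluded for the number of gene lists past camera, and the splits cannot decide it. Of the 35 splits, 5 gave 12 or more, and the highest of the others gave 14. The others with 12 or more each held 3 P1 arrays and 1 P21 array on 1 side, which keeps part of the age difference. The 8 splits that part every same-numbered pair, as the real one does, are by themselves too few for a share under 5%. Of these, the other 7 gave 1 to 14 lists and called at most 0 probe sets, and the 27 that keep a pair together gave up to 13 lists.

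Of 25 oligodendrocyte and myelin genes, 20 rose in a sample meant to hold motoneurons, and the median over the list was 1.61. A lower share of motoneuron RNA at P21 that raised markers of all other cells alike is argued against as the whole cause, but by 1 comparison only. The myelin median exceeded the astrocyte median by 1.25 (95% bootstrap interval over genes 0.870 to 1.98, which takes genes as independent). The other lists were not compared in this way. Their medians were 1.05 (microglial), 0.76 (erythrocyte), 0.63 (endothelial), 0.52 (Schwann cell), -0.07 (precursor), -0.11 (dividing cell) and -0.53 (interneuron). The bootstrap intervals of the microglial median (0.474 to 1.27) and the myelin median (1.25 to 2.20) overlapped. RNA of other cells need not rise alike, so a gain that was larger for oligodendrocytes stays open. Values near 0 are argued against too, since the myelin median was 1.57 with a pseudocount of 64. RNA of mature oligodendrocytes or their processes captured with the cells may contribute and cannot be told apart from a change in the motoneurons themselves. Of the 25 members, counted without the filter, 3 lay below its level on all P1 arrays, and 100% of these rose. Such genes would rise under either explanation, so their count cannot decide between them, whatever their number. The myelin genes Mbp and Mobp reached 8290 and 4598 at P21. The labels name a cresyl violet stain and no marker for choosing the cells, and the list shares Sox10 and Hapln2 with other lists. The age of the animals stays an open explanation that was not tested.

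Many of the falling lists hold bright genes, and the median change ran from 0.12 in the dimmest 10% of probe sets to -0.07 in the brightest, so an intensity-dependent scaling of the arrays could lower a bright list. It is argued against as the whole cause for ribosomal protein genes, whose median stood at percentile 0.12 of 10000 random lists matched on mean level. The same holds for axon growth, axon guidance and developmental transcription factor genes, each at percentile 0. Lists matched to axon guidance and transcription factor genes had medians of 0.053 and 0.065, so scaling by level would not lower those 2. The random lists take genes as independent, whereas the estimated correlation among ribosomal genes was 0.713. Another split of the arrays gave the ribosomal list a median of size 0.177, against -0.176 in the real one, so its percentile is weak evidence. For oxidative phosphorylation (percentile 42.5) and glycolysis (14.3) the medians are consistent with that scaling. For the 4 lists where scaling is argued against, correlation between genes and the age of the animals stay open. For axon guidance and transcription factor genes so does a smaller share of other neurons' RNA at P21. The interneuron list had a median of -0.53, although it did not pass camera (adjusted p = 0.0722).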

How the results depend on the processing

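Where a called result had a value under an alternative, its direction stayed, and 0 of the called probe sets shared with an alternative had the opposite sign in it. The 2 settings that use 4 arrays, the leave-outs on the same probe sets and the Eif2s3y covariate were chosen after seeing the data. The number of called probe sets was 3385 with only the arrays numbered 1 and 2, and 1070 of these changed at least 2-fold. With only those numbered 3 and 4 the counts were 5834 and 1358. The signs of the correlations between the arrays' deviations followed the same grouping, and the cause was not tested. The share of calls higher at P21 was 38.6% when each array was centred on its median, where the construction moves every change by the difference of the medians, and 66.2% with only the arrays numbered 3 and 4, where the cause was not tested. Camera with an estimated correlation passed 0 lists, with 3 at an unadjusted p under 0.05. Correlation alone does not account for the lost calls. The erythrocyte list had an estimated correlation of -0.045, below the preset 0.01, yet its unadjusted camera p went from 0.00628 to 0.0306. Fry, which does not set a list against other genes, passed 22. Leaving out 1 array at a time gave 5610 to 7419 probe sets, 1633 to 2034 changed at least 2-fold, a share of 48.4% to 59.2% and 9 to 15 lists. The replicate block called 8805 probe sets and 12 lists, and of the named results it changed no call but that of Gad1. Of 121 named genes, all had a value in the leave-outs on the same probe sets. With the filter applied anew, 100 had one without a P1 array, 107 without a P21 array, and 71 and 73 with only arrays 1 and 2 or 3 and 4, since genes bright at 1 age alone, most of the leading genes among them, drop out there. The filter at the 60th percentile kept 103, without the dimmer genes. Of the 114 called, 4 lost the call in at least 1 leave-out and 19 under another alternative, among those with a value. Atp5f1a, Rpl4, Rpl7, Tnc, Sox10, Col1a1, Col1a2, Prx and Gap43 lost it only with 4 arrays. Of the 12 lists, 4 and 7 did so with the preset correlation, and all 12 with the estimated one. The developmental transcription factor, erythrocyte, endothelial, oxidative phosphorylation and glycolysis lists also lost the call with 4 arrays. The signal over background limits dim genes, since no detection calls were used here and intensities below the filter level bound a fold without measuring it.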

Other observations

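The relation of Eif2s3y to Xist and the Eif2s3y covariate were tests chosen after the values were seen, and so were the genes named in this part. Outside the lists, the co-chaperone gene Bag3 rose from 395 ± 35.3 to 5458 ± 211 (change 3.74 ± 0.09, adjusted p = 2.17e-08, n = 4 per age, limma), and Hspb8, whose protein binds BAG3, rose from 429.9 ± 215 to 2995 ± 456. Hopx rose by 3.18 ± 0.17, the anoctamin gene Ano3 by 3.33 ± 0.10 and the prohormone convertase gene Pcsk2 rose at least 4.00-fold. Fgf21, a secreted growth factor gene, went from 60.3 ± 10.5 to 1013 ± 204, at least 3.79-fold. Among falls, Synpr, a synaptic vesicle protein, went from 2704 ± 241 to 169 ± 41.5, at least 9.33-fold, the muscarinic receptor gene Chrm3 fell at least 6.39-fold and Dapk1 at least 6.46-fold. Crabp1, which binds retinoic acid, fell from 4593 ± 321 to 705 ± 228 and Bex1 from 5147 ± 159 to 947 ± 323.

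Some genes had probe sets that moved apart. Of 2494 genes with several kept probe sets, 614 had at least 2 called, 66 had calls in opposite directions, and in 4 both changed at least 2-fold, Brms1, Crebl2, Myo16 and Ncam1. For Ncam1, a cell adhesion molecule with several splice forms, 1 probe set rose from 1104 ± 155 to 2241 ± 201 and another fell from 2447 ± 218 to 756 ± 254. For Myo16, 1 rose by 1.05 and another fell from 1094 ± 204 to -86.1 ± 54.1. Which transcripts the probe sets read was not analysed here.

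Eif2s3y, which lies on the Y chromosome, read 902, 21.5, 1708 and 977.5 on P1 replicates 1 to 4 and 2486, 2017, 692 and 19.3 on P21 replicates 1 to 4. Xist, expressed from the inactive X, ran opposite to it over the 8 arrays (Spearman rho -0.905, exact permutation p = 0.00456, adjusted 0.00913 over the 2 relations computed; Pearson r of the log2 levels -0.684, exact permutation p = 0.0634, adjusted 0.127). Without P21 replicate 4 and P1 replicate 2, the 2 arrays farthest from the median log2 level of Eif2s3y, that r was -0.888, and on the deposited intensities of all 8 it was -0.952. The relation is consistent with pools that differ in their shares of male and female rats, a hypothesis, although the probe set of the Y-linked gene Uty did not follow Eif2s3y (rho -0.405, exact permutation p = 0.327). With the level of Eif2s3y as a covariate, 7588 probe sets passed.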
